A study of Rattus norvegicus with 6 samples.

How the data were processed

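RNA pools from esophageal mucosa of 3 BRB and 3 BRB+NMBA pools were measured on 6 Agilent rat 44K 2-colour arrays, 1 array per slide. Per the labels' protocols, RNA was labelled with the Agilent Low Input Fluorescent Linear Amplification Kit, the esophagus pool with Cy5 and a universal rat reference RNA with Cy3. Per the file headers, the arrays were read with Feature Extraction 7.5.1, which gives for each spot the mean and background intensity of both dyes, processed signals, quality marks and a log10 ratio of Cy5 over Cy3. The deposited series matrix of log10 ratios equalled the scanner's log10 ratios to within 0.005 in every column. Its column medians were -0.0677, -0.0655 and -0.0638 in the BRB pools and 0 in each BRB+NMBA pool. Scale and direction of that matrix follow from this match; the origin of its centring stays unknown.

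Each array held 43628 spots, 41372 of them not controls, for 41012 probes. Probes were named through a table of the GRCr8 assembly, used for names only: 8121 by accession, 8672 by gene identifier, 1359 by symbol and 400 by synonym. The name in the file was kept for 4882 probes, and 17578 had no gene name.

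Mean intensities were corrected for background with normexp (offset 50) on all spots and normalized by loess within each array with control spots at weight 0, with limma 3.58.1 in R 4.3.3; files were read with data.table (version 1.17.8). Control spots and outlier spots were left out, saturated spots kept, and spots of 1 probe averaged. Probes were kept when well above background in Cy5 on at least 3 of 6 arrays. A gene was represented by the probe with the highest mean Cy5 signal; probes with no gene name stayed as features of their own. This left 34147 features, 18838 with a gene symbol and 15309 without. For single channels, Cy5 or Cy3 intensities after normexp were quantile normalized between arrays. All differences are BRB+NMBA minus BRB on the log2 scale with the offset included, which makes differences of dim features smaller. Values before loess or before normalization are those after normexp. Signal over background and the number of arrays limit the precision.

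Groups were compared with limma's lmFit and eBayes, 3 pools against 3, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. The same test on Cy3, where every array should carry the same RNA, served as a negative control. Gene lists were tested with camera at a preset correlation of 0.01 when they had at least 5 measured members, with camera at an estimated correlation and fry as alternatives; fry tests whether the genes of a list move on balance in 1 direction, not against other genes. The 28 lists, the ratio comparison, the negative control, the rule for naming genes and most alternatives were fixed before the data were examined. The Cy5 channel alone was among those alternatives; its use as the basis for the gene account, and the alternatives run on it, were chosen after the Cy3 result was seen.

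Named genes were the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, Cdkn1a, Mdm2, Ccng1, Mgmt, Cyp2a3, Ptgs2, Nos2 and Jun wherever measured, and up to 4 members of each list with the smallest adjusted p. Genes outside this rule are said to be so where they appear. Where a named gene had several tested probes, the others are given too.

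Alternatives covered background correction, normalization, the filter on dim probes, probes per gene, the variance model, array weights and the source of values. Others used the mean of the skeletal muscle list as a covariate or left out each pool. Another took extraction day, meaning the day of array processing, as a random block (duplicateCorrelation). Further ones took the Cy3 level of each feature out of its Cy5 values, kept only features with a Cy3 difference under 0.5 (by quantile-normalized or by median-centred Cy3), or subtracted a leak of Cy3 into Cy5. Camera with an estimated correlation was also run with each pool left out, with the muscle covariate, with Cy3 levels taken out and with Cy3 differences under 0.5; ranges of its adjusted p cover these settings and the reported one. The leak was first set at 2.70% of Cy3 on every array. On the BRB+NMBA arrays the lowest Cy5 to Cy3 shares among spots with Cy3 above 3000 were 2.07% to 2.70%, which bounds a linear leak there; on the BRB arrays they were 15.4% to 20.1%, which hardly bounds it. Control spots with a Cy3 oligo gave larger slopes of Cy5 on Cy3, 3.45% to 5.22% on the BRB arrays and 3.09% to 5.42% on the BRB+NMBA arrays, above the bound of the latter. The leak was therefore also subtracted at each array's control slope, and at 2.70% on the BRB+NMBA arrays alone. All 3 settings, and these further runs of camera, were chosen after the data were seen.

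The steps were tested on simulated data with 34011 features. In Cy5, limma recovered 8% of features changed 1.25-fold, 56% of those changed 1.5-fold, 90% of those changed 2-fold and 98% of those changed 4-fold, with 3 false calls. In the ratio it recovered 30%, 80%, 94% and 98%, with 6 false calls. At each size 50 features were changed, far fewer than the 10711 that passed in the real Cy5 comparison. The adjusted threshold was therefore stricter in the simulation, and these shares are not the sensitivity of the real comparisons. A list shifted by 0.3 passed camera in both, and 0 of the 27 other lists passed. Noise was drawn independently for each feature, so this run cannot show how often camera passes lists whose genes move together.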

Results

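Gene expression was measured in esophageal mucosa of rats on a diet with 5% black raspberries (BRB), with and without the carcinogen N-nitrosomethylbenzylamine (NMBA). NMBA is a nitrosamine that alkylates DNA and induces squamous tumours of the rat esophagus. After 2 weeks on the diet the BRB group received 3 injections of vehicle (20% DMSO), and the BRB+NMBA group 3 injections of NMBA at 0.5 mg/kg. Tissue was taken 24 h after the last injection and freed of submucosa and muscle before RNA extraction. Each group of 9 animals was divided into 3 RNA pools of separate animals: pools 7, 8 and 9 for BRB and pools 10, 11 and 12 for BRB+NMBA. Every pool was labelled with Cy5 and hybridized to its own 2-colour array together with a commercial rat reference RNA labelled with Cy3, and no array had the dyes swapped. The study also had rats on a control diet with and without NMBA; their arrays are not analysed here.

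The esophagus channel, Cy5, was of similar brightness in both groups. On average 88.8% ± 2.93 (SD, n = 3) of the spots were well above background in Cy5 on the BRB arrays and 87.2% ± 1.47 (SD, n = 3) on the BRB+NMBA arrays. The median Cy5 signal over background was 93.7 ± 19.4 (SD, n = 3) in BRB and 78.5 ± 9.93 (SD, n = 3) in BRB+NMBA. The reference channel, Cy3, was dimmer on the BRB arrays, at 36.5 ± 5.65 (SD, n = 3), than on the BRB+NMBA arrays, at 105 ± 1.22 (SD, n = 3). Precision is limited by the number of arrays. Across probes, which are not independent replicates, Cy5 signals of a BRB and a BRB+NMBA array correlated at r between 0.967 and 0.977, and the Cy3 reference signals at r between 0.550 and 0.579. Within a group, Cy3 signals correlated at r of at least 0.986.

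The first comparison asked which genes NMBA changed in raspberry-fed rats, by the ratio of each pool to the reference, BRB+NMBA minus BRB. By this ratio the ribosomal protein genes Rpl9 and Rps24, the matrix genes Bgn (biglycan) and Col1a1 (a collagen chain) and the calcium-binding protein gene S100a4 were lower in BRB+NMBA. The small GTPase gene Rab15, the phosphatase gene Dusp8, the transcription factor gene Hes7 and the neurotrophic factor gene Gdnf were higher, as was 1 of 3 probes of the small GTPase gene Cdc42. The Cy5 signal of the esophagus itself did not pass the test for Rpl9, Rps24, Bgn, Col1a1, Hes7, Cdc42 or Gdnf. In Cy5 S100a4 rose by 1.03 (other probes 0.64, past the threshold, and -0.07, not past it) and Dusp8 fell by 0.80, both opposite to the ratio, and Rab15 rose by 1.31, though its second probe did not pass. Of the 20 largest ratio differences, 7 passed in Cy5 with the opposite sign, 3 with the same sign and 10 did not pass. The Cy3 reference, after normalization, differed by -4.49 and -4.08 for Gdnf and Cdc42 and by 5.68 to 6.40 for Rps24, Col1a1 and Bgn.

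The ratio of Bgn fell by 6.16 on the log2 scale (limma adjusted p 1.16e-09), while its normalized Cy3 signal was higher by 6.40 and its Cy5 signal differed by 0.03 (adjusted p 0.928). Col1a1 fell by 5.96 in the ratio with a Cy3 difference of 6.37. Before loess the ratios of Bgn and Col1a1 differed by -8.43 and -8.81. The ratio of Hes7 rose by 6.66 (adjusted p 1.02e-07) and that of the probe used for Cdc42 by 6.39, but before loess they differed by 1.43 and 1.74. Their Cy3 differences were -3.56 and -4.08, and -1.72 and -1.98 before normalization, while Hes7 differed by -0.11 in Cy5 (adjusted p 0.537). The rest of the 10 largest falls were Rpl9, Rpl30-ps7, Rpl37l1, S100a4, Rps27, Rps24, Rps12-ps5 and H3f3b, and the rest of the 10 largest rises were Dusp8, Rab15, Gdnf, Scaf1, Col4a1, Msl3l2, Inhbb and Plekho2. All 20 had a Cy3 difference opposite in sign to the ratio, from -4.95 to -2.61 for the rises and from 5.02 to 7.45 for the falls. Of the 6 of these genes with several probes, 3 had a probe of the opposite sign: the other probes of Cdc42 lay at -1.62 and -1.75, that of Col4a1 at -2.42 and that of Inhbb at -0.12. The other probe of Col1a1 lay at -0.99, that of Rab15 at 0.31 and those of S100a4 at -4.23 and -0.33. Before loess the ratios of the 10 rises differed by 0.83 to 2.04 and those of the 10 falls by -8.87 to -7.58. Loess moved the difference of the 341 brightest features by a median of 3.13 and that of the 17005 dimmest by 0.69, so the sizes given here depend on it. The scanner marked Cy3 as saturated for Dusp8 on 3 of 3 BRB arrays and for Hes7 on 1, and for Rpl37l1 on 3 of 3 BRB+NMBA arrays, for S100a4 on 2 and for Rpl9 on 1. The sizes of the Cy3 and ratio differences of these 5 genes are therefore limited by saturation.

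Of 34147 features tested by limma, 26769 differed in the ratio, 12845 higher and 13924 lower, and 7803 of them at least 2-fold. The Cy3 reference, which was to be the same RNA on every array, differed for 27469 features by the same test, 11142 higher and 16327 lower in BRB+NMBA. Across features the ratio and Cy3 differences correlated at r = -0.940, and the ratio and Cy5 differences at r = -0.375. Of the features that passed in both the ratio and Cy5, 1565 had the same sign and 7976 opposite signs.

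In the ratio 15 of 28 gene lists passed camera's test with a preset correlation, 3 of them upward and 12 downward. The downward lists included cytosolic ribosomal proteins, with a median ratio difference of -3.68 (adjusted p 1.34e-11, and 0.444 with an estimated correlation), and oxidative phosphorylation, at -3.23 (adjusted p 2.57e-13, and 0.247 with an estimated correlation). In Cy3 the medians of these lists differed by 4.00 and 2.93. The upward lists were squamous differentiation and cornification, endothelial markers, and airway and glandular epithelium markers, with median ratio differences of 0.44, 0.41 and 0.35, Cy3 medians of -0.25, -0.58 and -0.57, and adjusted p with an estimated correlation of 0.247, 0.444 and 0.247. The other downward lists were fibroblast markers, sterol synthesis, heat shock, phase II, DNA repair, apoptosis, G2/M, inflammation, growth factor and S phase genes, with medians from -1.68 to -0.49 and adjusted p with an estimated correlation from 0.247 to 0.603. With a correlation estimated from the data, camera passed 0 of the 15, with a lowest adjusted p of 0.247 and 5 lists at an unadjusted p under 0.05, while fry passed 25 lists.

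**Figure D1:**
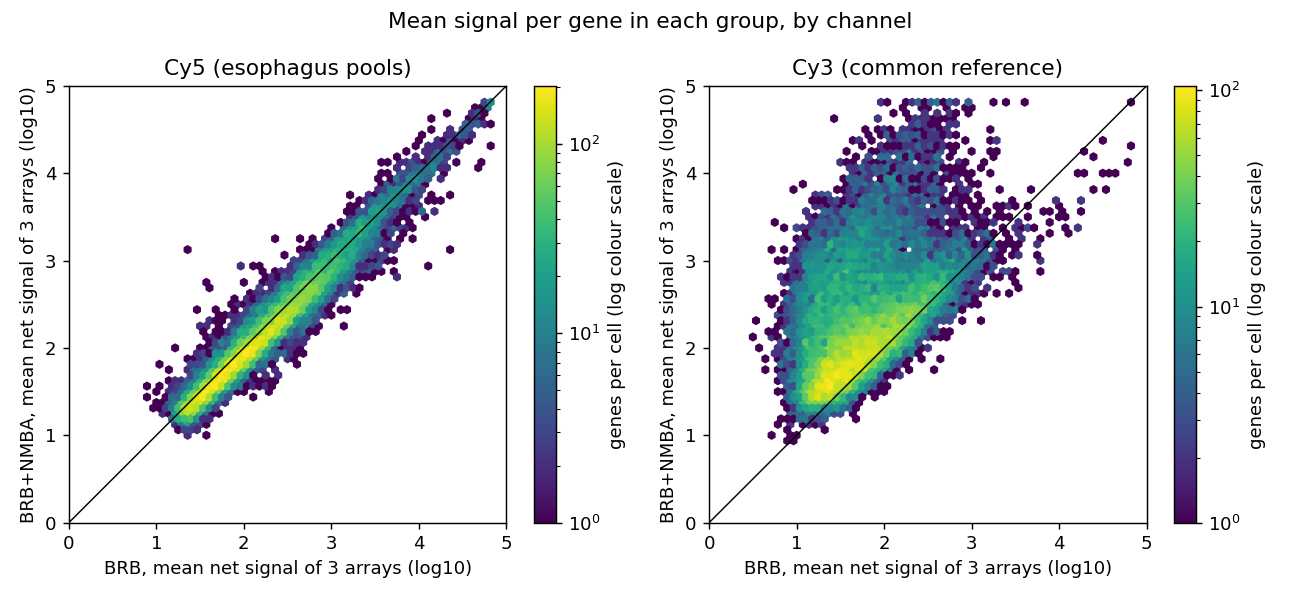
Mean net signal per gene (log10 axes) in BRB against BRB+NMBA, left in Cy5 (esophagus pools) and right in Cy3 (common reference), with colour giving genes per cell on a log scale and the line marking equal signal. The Cy5 cloud lies along the line, and the Cy3 cloud spreads away from it, with 27469 of 34147 features differing in Cy3.

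The second comparison used the Cy5 channel alone, an alternative fixed in advance; it was taken as the basis for the account of genes below only after the Cy3 result was seen. NMBA-treated mucosa had higher Cy5 signal for the keratin genes Krt14 and Krt5 of the basal layer, the kallikrein protease genes Klk6 and Klk7, the protease inhibitor gene Serpinb12, the growth factor gene Areg and Fgf13, which encodes an intracellular FGF homologous factor. The p53 target genes Ccng1, Plk2 and Cdkn1a also rose, as did the replication gene Rrm2. The metabolic genes Aldh3a1, Ces1d, Cyp2f4 and Gsta3l1 and the skeletal muscle genes Myl3, Myh8, Actn3 and Mybpc1 fell. After quantile normalization, on which the Cy3 differences below rest, Cy3 differed by -0.64 to 0.42 for Krt14, Krt5, Klk7, Serpinb12, Fgf13, Rrm2, Aldh3a1 and Myl3, but this depends on the scaling. With Cy3 centred on its median the difference was 2.23 for Krt14, 1.62 for Krt5, 1.10 for Rrm2 and 1.97 for Aldh3a1, and between -0.37 and 0.0092 for Klk7, Serpinb12, Fgf13 and Myl3. Before normalization Cy3 was higher in BRB+NMBA for all 8, by 0.53 to 3.13, against a median of 0.64 over all features.

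In Cy5, 10711 features differed (limma), 5609 higher and 5102 lower in BRB+NMBA. Of these, 317 rose and 370 fell at least 2-fold. Among the 18838 features with a gene symbol, 3535 rose and 3038 fell. The 3 arrays of one group lay wholly above those of the other for 45.9% of features, where chance gives 10%. The Cy5 and Cy3 differences correlated at r = 0.597 across features, which are not independent replicates (0.504 with median-centred Cy3), and 89.9% of the features that passed in Cy5 had the same sign in Cy3, against 74.6% of all features. Of 128 genes of the naming rule that passed in Cy5, 92 had the opposite sign in the ratio. Of the 34147 features, 14286 had a Cy3 difference under 0.5, and 1220 of these passed, 756 higher and 464 lower; by median-centred Cy3 these counts were 12499 and 1436. No day of array processing held both groups (the BRB arrays fell on 1 day, the BRB+NMBA arrays on the other 2), so no value within a day could be had. With day as a random block 11702 features differed. Since no day held both groups, such a block cannot take a day effect out of the group difference.

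The largest rise in Cy5 was that of Spp1 (osteopontin, a secreted phosphoprotein), by 4.27 ± 0.06 on the log2 scale (SE, n = 3 pools per group, limma adjusted p 1.59e-08), with a Cy3 difference of 4.72. Krt7 and Krt18, keratins of simple epithelia, rose by 3.05 ± 0.09 and 2.68 ± 0.07, with Cy3 differences of 4.03 and 4.94. A second probe of Krt18 differed by -0.11 in Cy5 and -0.95 in Cy3, and the first lay at 1.17 once a leak of 2.70% of Cy3 was subtracted and at -0.36 with a larger leak taken from control oligos. Retn (resistin), Ripk3 (a kinase of necroptosis) and Ka11 rose by 2.75, 2.75 and 2.90, with Cy3 differences of 4.63, 3.07 and 1.95. Klk6 rose by 2.71 ± 0.17 (adjusted p 2.75e-05) and Areg (amphiregulin, a ligand of the EGF receptor) by 2.33 ± 0.13 (adjusted p 1.88e-05), with smaller Cy3 differences of 0.89 and 1.39. Fgf13 rose by 2.20 ± 0.07 (adjusted p 2.17e-06) and Dnase1l3, which encodes a secreted DNase, by 2.09 ± 0.06 (adjusted p 1.36e-06), with Cy3 differences of 0.20 and 0.39.

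The largest fall was that of Gsta3l1, a glutathione transferase gene, by 3.81 ± 0.48 (SE, n = 3 pools per group, limma adjusted p 6.20e-04), with a Cy3 difference of -1.54. Hmmr, a hyaluronan receptor gene active in mitosis, fell by 2.85 and Rabif fell by 2.63, with Cy3 differences of -4.90 and -5.11; the other probes of Rabif lay at -2.66 and -0.37. Cpz (carboxypeptidase Z) fell by 2.50 and Dapl1 fell by 2.28, with Cy3 differences of -1.66 and -1.98. Actc1, Myh8, Myl3, Apobec2 and Actn3, genes of striated muscle, fell by 2.68, 2.36, 2.30, 2.23 and 2.02 with adjusted p from 0.00928 to 0.0137, and Cy3 differences from -2.73 to -0.08. With a trended and robust variance in limma these 5 did not pass, and Myh8 did not pass without BRB pool 8 (-2.21). With the mean of the skeletal muscle list as a covariate the 5 muscle genes lay between -0.07 and 0.15. That list holds Myh8, Myl3 and Actn3, so the loss of their difference was fixed in advance and shows nothing about its cause.

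Among p53 targets and DNA damage response genes, 36 of 45 measured, 17 rose, 4 fell and 15 did not pass; adjusted over the list alone, 18 rose and 4 fell. The proapoptotic gene Bbc3 rose by 1.71 ± 0.06 (SE, n = 3 pools per group), Btg2 by 1.54 ± 0.10, the cyclin gene Ccng1 by 1.54 ± 0.09 (1.07 for its second probe) and the kinase gene Plk2 by 1.42 ± 0.07. Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 0.79 ± 0.06, and Mdm2, the negative regulator of p53, did not pass (0.23, limma adjusted p 0.0653). Mdm2 did pass without BRB+NMBA pool 11 (0.30), with a Cy3 leak of 2.70% or of the control oligos subtracted (0.25 and 0.27), with Agilent's processed Cy5 signal (0.41) and with Cy3 levels taken out (0.58). Cy3 differed by 3.13 for Bbc3, 4.15 for Btg2, 3.01 for Ccng1, 1.11 for Plk2, 0.68 for Cdkn1a and -1.67 for Mdm2. The list had a median of 0.21 in Cy5 (camera adjusted p 2.20e-04, and 0.164 with an estimated correlation) and 0.41 in Cy3. With the muscle covariate its Cy5 median was 0.23.

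Of 39 DNA repair genes measured, 17 rose, 4 fell and 18 did not pass; adjusted over the list alone, 18 rose and 5 fell. Mgmt, whose product removes alkyl groups from guanine, rose by 1.28 ± 0.09 (SE, n = 3 pools per group, limma adjusted p 4.02e-05), Fen1 (flap endonuclease) by 1.17 ± 0.07 and Tdg (thymine DNA glycosylase) by 0.74 ± 0.07. Their Cy3 differences were 3.36, 2.93 and 2.72. Second probes of Fen1 and Tdg, with Cy3 differences of -0.15 and 0.17, differed by 0.05 and 0.21 in Cy5 and did not pass. The repair list had a median of 0.16 in Cy5 and 0.75 in Cy3 (camera adjusted p 5.39e-04, and 0.212 with an estimated correlation). With Cy3 levels taken out the list no longer passed, at a median of 0.076, and Mgmt, Fen1 and Tdg lay at 0.71, 0.75 and 0.32.

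The replication gene Rrm2 and the cyclin genes Ccna2 and Ccnb1 rose, while the S phase and G2/M lists passed camera only with the preset correlation. The S phase list had medians of 0.43 in Cy5 and 0.55 in Cy3 (camera adjusted p 3.07e-11, and 0.164 with an estimated correlation). The G2/M list had medians of 0.62 and 0.79 (camera adjusted p 7.06e-12, and 0.166 with an estimated correlation). Over the 107 members of the S phase, G2/M and heat shock lists, the 28 whose quantile-normalized Cy3 was not higher had a median Cy5 difference of 0.00, with 14 higher, and the other 79 had one of 0.69. This split depends on the scaling: by median-centred Cy3 there were 18 such members, with a median of -0.018 and 8 higher, and before normalization 1. The split was also not matched for Cy5 brightness, and the offset makes differences of dim features smaller. Of 33 S phase and DNA replication genes, 24 rose, 1 fell and 8 did not pass; adjusted over the list alone, the counts were 24 and 1. Rrm2, a subunit of ribonucleotide reductase, rose by 1.33 ± 0.08 (SE, n = 3 pools per group, limma adjusted p 2.00e-05) with a Cy3 difference of 0.42, and the chromatin assembly gene Chaf1b by 1.41 ± 0.07 with one of 2.96. Of 40 G2/M and mitosis genes, 29 rose, 2 fell and 9 did not pass, and 29 and 3 adjusted over the list alone. The kinase gene Ttk and the cyclin genes Ccna2 and Ccnb1 rose by 1.72, 1.66 and 1.22, with Cy3 differences of 3.49, 2.85 and 2.22. Second probes of Ttk, Ccna2 and Ccnb1, with Cy3 differences of 0.98, 0.41 and 1.03, rose less, by 0.81, 0.53 and 0.53.

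The chaperone genes Hspa5 and Hspa8 rose, while the list of the heat shock and unfolded protein response passed camera only with the preset correlation. This list had medians of 0.56 in Cy5 and 1.48 in Cy3 (camera adjusted p 9.88e-12, and 0.164 with an estimated correlation). Among 34 genes of the heat shock and unfolded protein response, 26 rose, 1 fell and 7 did not pass, and 27 and 1 adjusted over the list alone. Hspa5, the chaperone of the endoplasmic reticulum, rose by 1.35 ± 0.07 and Hspa8, a cytosolic chaperone, by 1.18 ± 0.06 (SE, n = 3 pools per group), with Cy3 differences of 4.46 and 5.42. The other 3 probes of Hspa8 rose by 0.92 to 1.20 with Cy3 differences of 1.02 to 3.55. With the muscle covariate the medians of the S phase, G2/M and heat shock lists were 0.44, 0.46 and 0.60.

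The keratin genes Krt14 and Krt5, the inhibitor gene Serpinb12 and the protease gene Klk7 rose, while the basal squamous list did not pass. Among 22 basal squamous genes, 9 rose, 4 fell and 9 did not pass (list median 0.08, Cy3 -0.23, camera adjusted p 0.292); adjusted over the list alone, 9 rose and 7 fell. Krt14 rose by 1.74 ± 0.14 (SE, n = 3 pools per group, limma adjusted p 7.66e-05) with a Cy3 difference of -0.51 (2.23 when median-centred), and its second probe by 1.90 with one of 1.68. Krt5, the partner keratin of Krt14, rose by 1.13 ± 0.09 with a Cy3 difference of 0.27 (1.62 when median-centred). Among 40 squamous differentiation and cornification genes, 16 rose, 4 fell and 20 did not pass, and 18 and 4 adjusted over the list alone. Serpinb12 rose by 0.97 ± 0.09 and Klk7, a protease of cell shedding, by 0.58 ± 0.06, with Cy3 differences of -0.64 and -0.09. Spink7, a protease inhibitor gene, rose by 1.36 ± 0.07 with a Cy3 difference of 1.33 and was well above background on only 1 of 3 BRB arrays. The differentiation list had a median of 0.20 in Cy5 (camera adjusted p 0.00110, and 0.443 with an estimated correlation). In Cy3 its median was -0.25, or 0.06 when median-centred. With the muscle covariate the Cy5 median of the differentiation list was 0.18, and it no longer passed.

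Among 35 phase I metabolism genes, 2 rose, 17 fell and 16 did not pass; adjusted over the list alone, 2 rose and 18 fell. Cyp2f4, a cytochrome P450 gene, fell by 1.94 ± 0.19 (SE, n = 3 pools per group, limma adjusted p 1.91e-04), Aldh3a1, an aldehyde dehydrogenase gene, fell by 1.92 ± 0.14 (adjusted p 5.41e-05) and Ces1d, a carboxylesterase gene, fell by 1.24 ± 0.08. Cy3 differed by -1.49, -0.49 and -0.59 for these genes. Cyp2a3, a P450 gene linked to NMBA activation, was not among the features tested. The phase I list had medians of -0.24 in Cy5 (camera adjusted p 4.18e-04, and 0.164 with an estimated correlation) and -0.59 in Cy3. With the muscle covariate its Cy5 median was -0.21. Among 49 phase II and Nrf2 target genes, 11 rose, 12 fell and 26 did not pass, and 13 and 14 adjusted over the list alone. Akr1b8, an aldo-keto reductase gene, rose by 1.02 with a Cy3 difference of 2.53. One probe of the thioredoxin reductase gene Txnrd1 rose by 1.00 with a Cy3 difference of 0.29; its other probes differed by 0.30, which passed, and 0.10, which did not. The phase II list did not pass (median 0.00, Cy3 0.41, camera adjusted p 0.788).

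Of 43 growth factor, AP-1 and matrix remodelling genes, 15 rose, 5 fell and 23 did not pass, and 17 and 6 adjusted over the list alone. Fos rose by 1.56 ± 0.10, Atf3 by 1.09 ± 0.10 and Jun by 0.57 ± 0.06 (SE, n = 3 pools per group), with Cy3 differences of 2.53, 2.37 and 3.46; with Cy3 levels taken out Jun lay at 0.14 and no longer passed. The list had medians of 0.19 in Cy5 and 0.13 in Cy3 (camera adjusted p 0.00254, and 0.212 with an estimated correlation). Among 40 inflammation genes, 16 rose, 5 fell and 19 did not pass, and 16 and 7 adjusted over the list alone; the list did not pass (median 0.06, Cy3 0.48, camera adjusted p 0.0623), though it did without BRB pool 9 and without BRB+NMBA pool 11 or 12. With an estimated correlation its adjusted p was 0.440, and 0.251 to 0.785 over the settings. The chemokine genes Ccl3 and Cxcl1 rose by 1.73 and 1.71 with Cy3 differences of 3.13 and 4.64, and Cxcl1 lay at 0.56 once a leak of 2.70% of Cy3 was subtracted and at -0.31 with the control oligos' leak. Ccl20 fell by 1.22 ± 0.07 (adjusted p 1.64e-05) while its Cy3 signal was higher by 0.83. The cyclooxygenase gene Ptgs2 and the nitric oxide synthase gene Nos2 did not pass (0.14 and -0.02, limma adjusted p 0.345 and 0.886).

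Of 26 interferon response genes, 10 rose, 3 fell and 13 did not pass, with the same counts adjusted over the list alone. Cxcl10 and Isg15 rose by 1.11 and 0.86 with Cy3 differences of 1.42 and 0.50. The interferon list had medians of 0.16 in Cy5 and 0.51 in Cy3 (camera adjusted p 0.0378, and 0.278 with an estimated correlation). It no longer passed without BRB pool 7 (median 0.18), with Cy3 levels taken out (0.074), with no background subtraction (0.047) or with the mean of the probes of a gene (0.10). Among 40 apoptosis genes, 11 rose, 1 fell and 28 did not pass, again with the same counts adjusted over the list alone. Bax, a proapoptotic gene, rose by 0.73 with a Cy3 difference of 2.46, and its second probe by 0.71 with one of 2.19. The apoptosis list had medians of 0.11 and 0.57 (camera adjusted p 0.00205, and 0.375 with an estimated correlation), and no longer passed with Cy3 levels taken out (median 0.027). Of 42 oxidative phosphorylation genes, 16 rose, 2 fell and 24 did not pass, and 17 and 2 adjusted over the list alone. Cox6c rose by 0.59 with a Cy3 difference of 4.11, and the list had medians of 0.15 and 2.93 (camera adjusted p 0.00654, and 0.493 with an estimated correlation). With Cy3 levels taken out the direction of this list flips, to a median of -0.12 that passed downward with the preset correlation only (adjusted p 0.306 with an estimated one, and 0.306 to 0.636 over the settings). Under that setting Cox6c lay at 0.26 and no longer passed; with cyclic loess the list did not pass (0.097).

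The list of skeletal muscle markers was lower in BRB+NMBA by camera with the preset correlation (adjusted p 1.25e-07, and 0.443 with an estimated correlation). Of 38 measured, 0 rose, 27 fell and 11 did not pass; adjusted over the list alone, 1 rose and 29 fell. Mybpc1 fell by 1.84 ± 0.28 and Atp2a1, the calcium pump of fast fibres, fell by 1.18 ± 0.19 (SE, n = 3 pools per group), with Cy3 differences of -0.76 and -1.63; a second probe of Mybpc1 lay at -0.74. The list had medians of -0.83 in Cy5 and -0.76 in Cy3. Relative to the BRB mean, the medians of the BRB+NMBA pools were -1.24 in pool 10, -0.997 in pool 11 and -0.42 in pool 12, and the BRB pools lay between -0.06 and 0.13. Of 14 smooth muscle markers, 1 rose, 6 fell and 7 did not pass, with the same counts adjusted over the list alone (median -0.24, Cy3 -0.21, camera adjusted p 0.0623); the list passed without BRB pool 7 and without BRB+NMBA pool 10 (with an estimated correlation 0.394 to 0.852 over the settings). Among them the myosin gene Myh11 fell by 0.86, with a second probe at -0.46.

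The remaining lists did not pass camera's test in Cy5. Fibroblast and connective tissue markers had 2 up and 6 down of 31 (median -0.13, Cy3 1.28, adjusted p 0.222), with Mfap5 falling by 0.83; the list passed without BRB+NMBA pool 12 (with an estimated correlation 0.431 to 0.984 over the settings). Endothelial markers had 0 up and 5 down of 19 (-0.06, Cy3 -0.58, adjusted p 0.302), and 0 and 2 adjusted over the list alone. Macrophage, dendritic and neutrophil markers had 5 up and 3 down of 29 (0.09, Cy3 -0.49, adjusted p 0.501). Lymphocyte and mast cell markers had 5 up and 5 down of 28 (-0.01, Cy3 -0.30, adjusted p 0.999). Nerve and Schwann cell markers had 3 up and 4 down of 22 (-0.18, Cy3 -0.93, adjusted p 0.130), and 3 and 9 adjusted over the list alone. Adipocyte markers had 3 up and 3 down of 18 (0.01, Cy3 0.01, adjusted p 0.566), blood cell markers 1 up and 1 down of 10 (-0.07, Cy3 -1.02, adjusted p 0.845), and airway and glandular epithelium markers 6 up and 2 down of 26 (0.01, Cy3 -0.57, adjusted p 0.333).

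Among regulatory and housekeeping groups, circadian clock genes had 3 up and 4 down of 16 (median 0.00, Cy3 0.04, camera adjusted p 0.877), with the clock gene Bmal1 falling by 0.42. Glucocorticoid and fasting genes had 4 up and 5 down of 20 (-0.07, Cy3 0.06, adjusted p 0.867). Sterol and fatty acid synthesis genes had 6 up and 4 down of 31 (0.00, Cy3 1.12, adjusted p 0.877). Cytosolic ribosomal protein genes had 4 up and 5 down of 46, with a median of 0.01 in Cy5 against 4.00 in Cy3 (adjusted p 0.999); this direction flips with cyclic loess (-0.11). Adjusted over the list alone, 6 and 4 clock genes, 6 and 6 glucocorticoid genes, 6 and 4 sterol genes and 4 and 5 ribosomal genes rose and fell. The tissue marker counts were 2 and 6 for fibroblasts, 5 and 3 for macrophages, 5 and 5 for lymphocytes, 3 and 3 for adipocytes, 1 and 1 for blood and 7 and 2 for glandular epithelium.

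In Cy5, then, 12 of 28 lists passed with the preset correlation, 10 upward and 2 downward. With an estimated correlation camera passed 0 of them, with a lowest adjusted p of 0.164 and 6 lists at an unadjusted p under 0.05, and fry passed 18. With Cy3 levels taken out 14 lists passed, 8 upward and 6 downward: DNA repair, interferon and apoptosis genes no longer did, oxidative phosphorylation turned downward, basal squamous and glandular epithelium genes passed upward, and sterol synthesis, ribosomal protein and fibroblast genes passed downward. With an estimated correlation the adjusted p of these 14 were 0.131 to 0.538, so camera passed 0, with 7 lists at an unadjusted p under 0.05. The lists that passed both ways had medians of 0.17 for p53 targets, 0.28 for S phase, 0.45 for G2/M, 0.32 for heat shock, 0.28 for differentiation, 0.058 for growth factor, -0.13 for phase I and -0.77 for skeletal muscle genes with Cy3 levels taken out. With the muscle covariate 14 lists passed: differentiation and skeletal muscle no longer did, and inflammation, macrophage, fibroblast and smooth muscle genes did, at medians of 0.20, 0.41, 0.20 and -0.41. These 14 had adjusted p of 0.220 to 0.636 with an estimated correlation, so camera passed 0 there too, with 6 lists at an unadjusted p under 0.05. The covariate is the mean of the skeletal muscle list, so the loss of that list was fixed in advance. Medians and means of the tested lists had the same sign in Cy5 except for glucocorticoid, clock, lymphocyte and blood cell genes, where the test followed the mean for clock genes and the median for the others. In the ratio they differed for phase I, smooth muscle and macrophage genes, where the test followed the median.

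**Figure D2:**
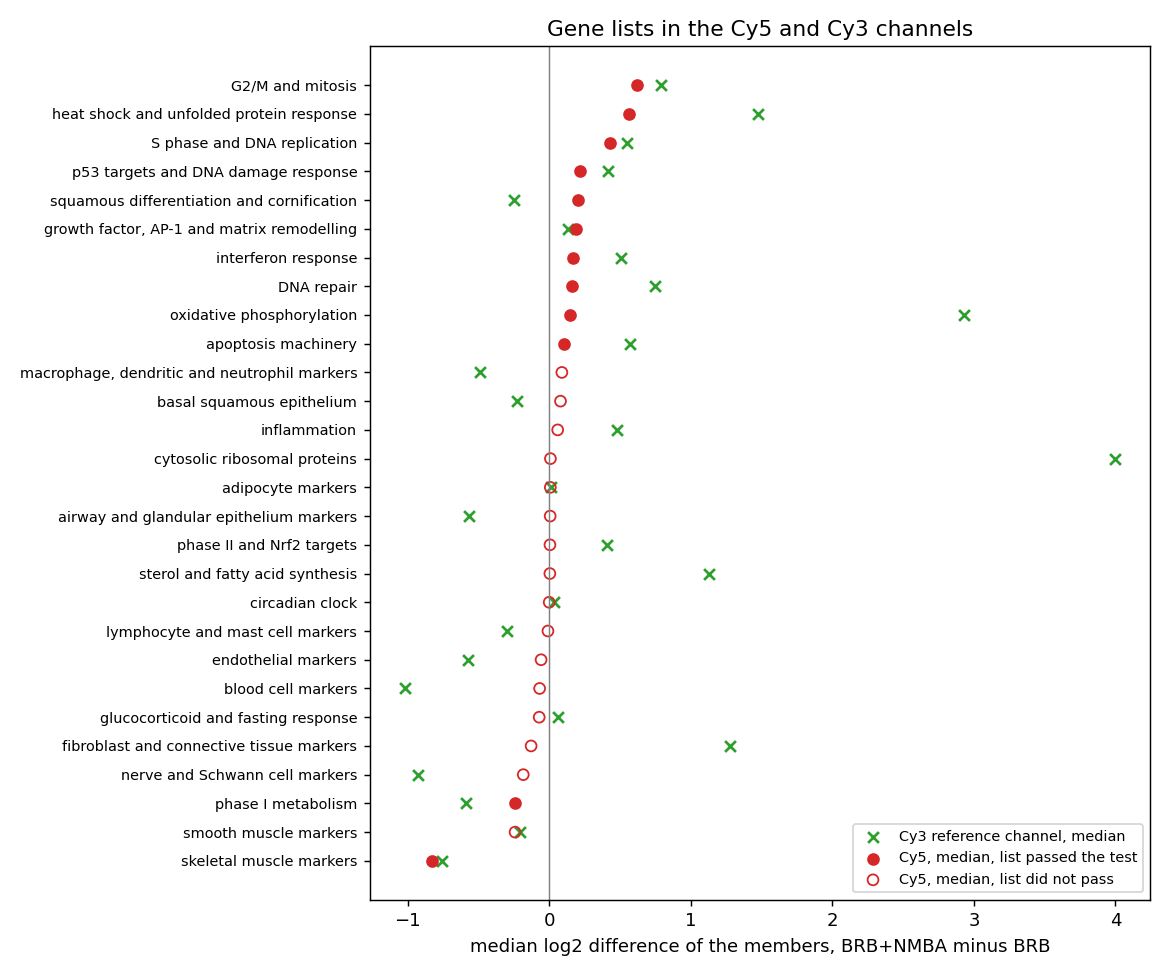
Median log2 difference (BRB+NMBA minus BRB) of each gene list in Cy5 (circles, filled where the list passed camera's test with the preset correlation) and in the Cy3 reference (crosses). Skeletal muscle markers lie at -0.83 and G2/M genes at 0.62 in Cy5, and ribosomal protein genes lie at 4.00 in Cy3 and 0.01 in Cy5, a sign that flips to -0.11 with cyclic loess.

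**Figure D3:**
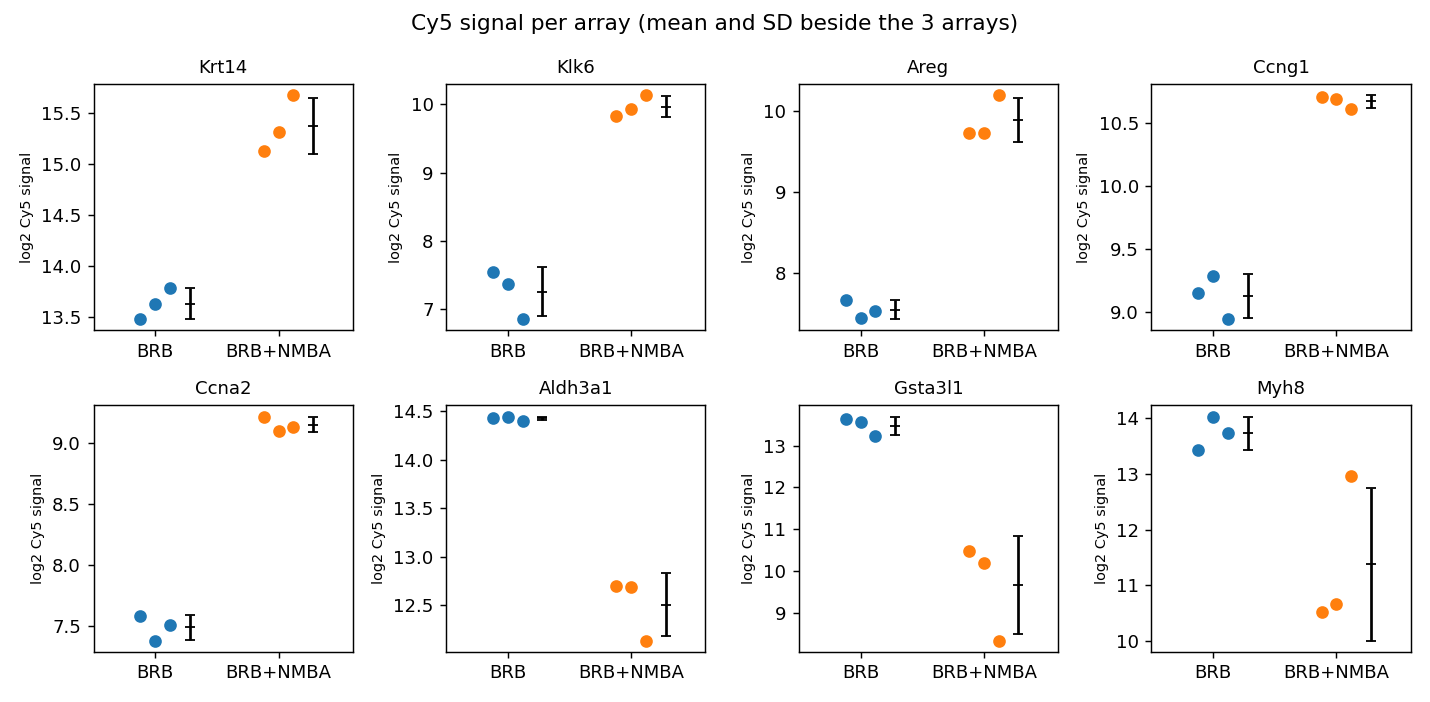
Normalized log2 Cy5 signal of 8 genes on each array, with the mean and SD (n = 3 pools per group) as a bar beside the points. For each gene the 3 arrays of one group lie above those of the other: Krt14, Klk6, Areg, Ccng1 and Ccna2 rose, and Aldh3a1, Gsta3l1 and Myh8 fell.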

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

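Every alternative of the Cy5 results, and extraction day as a random block for the ratio, was chosen after the Cy3 result was seen; the other alternatives of the ratio were planned.

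Among 24 alternatives, the ratio comparison gave 21421 to 28979 features in all but the Cy5 channel alone, which gave 10711. The number at least 2-fold was 3381 with no background subtraction, 17130 with Agilent's processed signals, 17130 with the series matrix values and 687 with the Cy5 channel alone. The lists passing were 0 with camera at an estimated correlation (5 at an unadjusted p under 0.05) and 25 with fry. Leaving out each pool in turn gave 25062 to 26742 features, 7682 to 8022 at least 2-fold, 14 to 15 lists and, in Cy3, 25803 to 27274 features. Aquantile after loess moved no ratio, so it shows nothing about stability. The share of higher calls was 48.0%, and 39.9% with median centring in place of loess, which moved the median of all features to -0.14, and 56.6% with processed signals, which moved it to 0.22.

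In Cy5, the count of features was 5081 with the muscle covariate, 5393 with Cy3 levels taken out, 1220 among features with a Cy3 difference under 0.5 and 1436 when this was judged by median-centred Cy3, 26769 for Cy5 over Cy3 and 6228 at an adjusted p of 0.01. The count at least 2-fold was 176 with no background subtraction, 1505 with Agilent's processed signal, 1091 with the muscle covariate, 349 with Cy3 levels taken out, 65 with a Cy3 difference under 0.5, 59 with it judged by median-centred Cy3 and 7803 for Cy5 over Cy3. Fewer features were tested with a Cy3 difference under 0.5, 14286, or 12499 by median-centred Cy3; the causes of the other shifts were not tested. The lists passing were 6 with a Cy3 difference under 0.5, 5 with it judged by median-centred Cy3 and 0 with camera at an estimated correlation (6 at an unadjusted p under 0.05; fry passed 18). Leaving out each pool gave 7472 to 10080 features, with the lowest count without BRB pool 8, 643 to 771 at least 2-fold and 12 to 14 lists.

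Of 1685 alternative values for the 72 genes whose Cy5 result the text names, 1618 were counted as unchanged, 21 were no longer past the threshold, 6 came past it and 40 reversed. Of 689 for the 28 list medians the counts were 622, 23, 24 and 20, and of 567 for 27 genes in the ratio 539, 7, 0 and 21. Unchanged values can include changes of sign where neither value passed. With Cy3 levels taken out the medians of endothelial and blood cell markers went from -0.058 and -0.069 to 0.091 and 0.109, and were not counted as reversed. Myh8 no longer passed without BRB pool 8, and the interferon list no longer passed without BRB pool 7. The 6 that came past it were all of Mdm2: without BRB+NMBA pool 11, with a Cy3 leak of 2.70% or of the control oligos subtracted, with Agilent's processed Cy5 signal, with Cy3 levels taken out and in Cy5 over Cy3. The inflammation list passed without BRB pool 9 and without BRB+NMBA pool 11 or 12, smooth muscle without BRB pool 7 and without BRB+NMBA pool 10, and fibroblasts without BRB+NMBA pool 12. Camera with an estimated correlation passed 0 lists with any 1 pool left out, with a lowest adjusted p of 0.0896 and 4 to 6 lists at an unadjusted p under 0.05, and 0 with the muscle covariate, with Cy3 levels taken out or with a Cy3 difference under 0.5 by either measure (6, 7, 2 and 2 at an unadjusted p under 0.05).

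The sizes of the 20 largest ratio differences moved with the processing while their directions held, except in the Cy5 channel alone. The 10 rises lay between 1.57 for Scaf1 and 2.78 for Gdnf with median centring, between 2.83 for Scaf1 and 4.04 for Gdnf with processed signals, and between 6.03 for Gdnf and 8.52 for Hes7 with no background subtraction. The 10 falls lay between -8.13 for Rpl9 and -6.85 for H3f3b with median centring, between -6.98 for Col1a1 and -6.24 for H3f3b with processed signals, and between -3.84 for Bgn and -2.73 for Rps27 with no background subtraction. With the mean of the probes of a gene Cdc42 lay at 1.003 and S100a4 at -3.46.

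Most counted reversals lay between the ratio and Cy5. For the 49 genes concerned, the ratio had its turned sign in 44 before loess and in 46 with median centring in place of loess; Cyp2f4, Atp2a1 and Myh8 turned only with loess. The causes were not tested further. Against the ratio, the Cy5 channel alone gave -0.11 for Hes7, -0.079 for Cdc42, -0.80 for Dusp8, -1.15 for Scaf1, -1.23 for Msl3l2, -0.71 for Inhbb, -1.08 for Plekho2, 0.026 for Bgn, 0.17 for Rpl9, 0.28 for Rpl37l1, 1.03 for S100a4, 0.013 for Rps24, 0.19 for Rps12-ps5, 0.68 for H3f3b, 0.79 for Cdkn1a, 1.54 for Ccng1, 1.28 for Mgmt, 0.14 for Ptgs2, -0.015 for Nos2 and 0.57 for Jun. Cdkn1a was at 0.11 in the ratio with scale after loess; the cause was not tested.

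Against Cy5, the ratio of Cy5 over Cy3 gave -1.90 for Spp1, -1.996 for Krt7, -2.96 for Retn, -0.89 for Ripk3, -3.66 for Krt18, 2.19 for Hmmr, 3.20 for Rabif, 0.96 for Myh8, -0.28 for Cdkn1a, -1.60 for Ccng1, -2.42 for Mgmt, -1.80 for Ptgs2, 0.59 for Nos2 and -3.66 for Jun. It gave -1.88 for Bbc3, -2.91 for Btg2, -2.34 for Fen1, -2.18 for Tdg, -1.98 for Chaf1b, -1.62 for Ccna2, -2.12 for Ttk, -1.45 for Ccnb1, -0.36 for Spink7, 0.63 for Cyp2f4, -2.07 for Akr1b8, -4.09 for Cxcl1, -2.14 for Ccl3, -0.71 for Cxcl10, -1.94 for Fos, -1.82 for Atf3, -2.33 for Bax, -3.67 for Hspa5, -4.52 for Hspa8, 0.061 for Atp2a1 and -4.04 for Cox6c.

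For list medians, Cy5 over Cy3 gave -0.25 for p53 targets, -0.74 for DNA repair, -0.49 for S phase, -0.68 for G2/M, 0.22 for phase I, -1.001 for phase II, -0.61 for inflammation, -0.42 for interferon, -0.51 for growth factors, -0.73 for apoptosis, -1.20 for heat shock, -1.58 for sterol synthesis, -3.23 for oxidative phosphorylation, -3.68 for ribosomal proteins and 0.41 for endothelial markers.

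Other counted reversals in Cy5 were Myh8 at 0.15, Myl3 at 0.042 and the fibroblast list at 0.20 with the muscle covariate, and Cxcl1 at -0.065, sterol synthesis at -0.15, oxidative phosphorylation at -0.12 and ribosomal proteins at -0.18 with Cy3 levels taken out. Sign changes where neither value passed, such as those of endothelial and blood cell markers, are not listed. With the leak at the control oligos' slopes Krt18 lay at -0.36 and Cxcl1 at -0.31; these slopes exceed the bound of the BRB+NMBA arrays. Ribosomal proteins lay at -0.11 with cyclic loess. The covariate is the muscle list itself, so it removes Myh8 and Myl3 by construction; the cause was not tested for the others.

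Extraction day as a fixed block was not run, since no day held both groups. No paired analysis was possible because the groups share no pool number and no animal. Dim features are limited by signal over background, since the offset of 50 makes their differences smaller.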

Other observations

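Tests on Cy3, on the leak, on the basal list, on day, on the spread of muscle markers and by median-centred Cy3, and all alternatives run on Cy5, were chosen only after the result was seen; the splits of the arrays and both tests on members whose Cy3 did not move the same way were not.

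Several genes outside the naming rule, chosen after their values were seen, had large Cy5 differences beside quantile-normalized Cy3 differences under 0.5 in size. Klk12, a kallikrein protease gene, rose by 1.89 ± 0.13 (SE, n = 3 pools per group, limma adjusted p 4.54e-05), Fetub, which encodes a secreted cystatin-family inhibitor, by 1.52 ± 0.06, and the water and glycerol channel gene Aqp3 by 1.26 ± 0.12. Their Cy3 differences were 0.41, -0.34 and -0.15. Serpinb3 and Rptn (repetin) rose by 1.08 each, with Cy3 differences of 0.45 and 0.31. The probe used for Cdkn1c, which encodes the cell cycle inhibitor p57, rose by 1.48; its other probes differed by 0.47 and -0.22. Hsd11b2, which inactivates corticosterone, fell by 1.46, Fxyd4, a regulator of the sodium pump, fell by 1.74 and Usp13, a deubiquitinase gene, fell by 1.75, with Cy3 differences of 0.16, -0.09 and -0.49. By median-centred Cy3 the differences were 0.82 for Klk12, 1.37 for Aqp3, 0.51 for Hsd11b2 and -0.63 for Usp13, and between -0.43 and 0.25 for Fetub, Serpinb3, Rptn and Fxyd4. No gene family is given a direction from these genes: of 18 Klk genes tested, 8 rose and 5 fell (family median 0.01, camera adjusted p 0.410).

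With features limited to a Cy3 difference under 0.5, 24 lists had enough members and 6 passed camera with the preset correlation. S phase genes had a median of 0.26 over 12 members, G2/M genes 0.16 over 11, differentiation genes 0.25 over 20, basal squamous genes 0.27 over 6 and DNA repair genes 0.08 over 15, while skeletal muscle markers lay at -0.69 over 12. With an estimated correlation the adjusted p was 0.219 for S phase genes and 0.432 for the other 5, so camera passed 0 of the 24 lists, with 2 at an unadjusted p under 0.05. By median-centred Cy3, 5 of 21 lists passed with the preset correlation: S phase, G2/M, differentiation and basal squamous genes at medians of 0.26, 0.15, 0.15 and 0.24, and skeletal muscle markers at -0.69. With an estimated correlation each had an adjusted p of 0.468, and camera passed 0 of the 21, with 2 at an unadjusted p under 0.05. Day and group stay confounded there too.

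The Cy3 reference signals differed between the groups. The highest rank correlation between a BRB and a BRB+NMBA array was 0.636, against a lowest value within a group of 0.975, which argues against overall brightness or scanner gain. Cy3 of ribosomal protein genes was 1.39% of Cy5 on the BRB arrays, against 46.8% over all features, which argues against Cy5 leaking into Cy3 on those arrays. A leak of Cy5 into Cy3 on the BRB+NMBA arrays was not tested. Across probes, Cy5 and Cy3 of the same array correlated at r of 0.951 to 0.953 on the BRB+NMBA arrays and 0.697 to 0.712 on the BRB arrays. Between groups Cy3 reached r of at most 0.579, while Cy5 reached at least 0.967, as other reference material or labelling in 1 set of arrays would give, a candidate explanation. Per the labels the reference was a universal rat RNA and not RNA of any pool. Whether this held on both sets of arrays was not tested, and neither was any biological explanation.

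The 107 members of the S phase, G2/M and heat shock lists had a median Cy5 rise of 0.56. After a leak of Cy3 was subtracted in 3 ways the median was 0.52 with the control oligos' slopes and 0.55 with each of the others. This argues against a linear leak as the whole cause. Before subtraction the median exceeded that of the basal squamous list by 0.48 (permutation p 0.00184, two-sided, 100000 resamples), so the basal list did not rise alike. The 3 lists had the lowest camera p of all lists in these same Cy5 values, where the basal list did not pass. The comparison was chosen after that, so a gap between them was favoured beforehand. The permutation treats genes on the same arrays as independent, and the lists also differed in Cy3. The permutation therefore does not settle whether a lower share of muscle contributed. The splits by Cy3 that follow were not matched for Cy5 brightness, and the offset makes differences of dim features smaller. The 28 members whose quantile-normalized Cy3 did not rise had a median of 0.00279, with 14 higher (exact sign test p 1, two-sided), and the 18 by median-centred Cy3 had one of -0.018, with 8 higher. With Cy3 levels taken out the S phase, G2/M and heat shock lists passed with the preset correlation at medians of 0.28, 0.45 and 0.32 (adjusted p 0.132 each with an estimated one, and 0.0896 to 0.649 over the settings), which goes the other way, so a probe effect shared by both dyes and a response to NMBA cannot be told apart for these lists. Days that hold both groups numbered 0, so extraction day cannot be told apart from group either. With day as a random block 12 lists passed in Cy5, but this block cannot take a day effect out of the group difference. The effect of NMBA stays among the open explanations.

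Skeletal muscle markers fell by a median of 0.83 in BRB+NMBA. Their pool medians spread over 0.82 in BRB+NMBA against 0.19 in BRB, where the groups differed by 0.89. The spread in BRB+NMBA came mostly from pool 12, whose median lay nearest to BRB and which was alone on its day of array processing. Muscle carried along to a different extent in each pool may account for the fall, but this spread cannot be told apart from day. The 10 members whose quantile-normalized Cy3 did not fall had a median of -0.51, with 4 higher (exact sign test p 0.754, two-sided). The 9 by median-centred Cy3 had one of -1.65, with 2 higher. Before normalization, where Cy3 of all features differed by a median of 0.64, there were 28 such members, with a median of -0.69 and 4 higher. The split depends on the scaling, which leaves a probe effect shared by both dyes open. An effect of NMBA on muscle was not tested apart from these.

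The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 26769 features in the ratio, 7803 of them at least 2-fold, 27469 in Cy3, 10711 in Cy5 and 687 at least 2-fold in Cy5; the highest of the other splits was 0 for each, and 1 of the 10 splits, the real one, gave a count as large. At an unadjusted p under 0.05, limma gave 27189, 27840 and 14304 features in the ratio, Cy3 and Cy5, and the other splits gave 5 to 80, 0 to 57 and 301 to 836. Each other split has arrays of both groups on each side, so the group difference widens the spread within sides and lowers these counts. They do not show what a comparison without any difference would give. For lists, the real split gave 15 in the ratio and the highest other 15, with 4 splits as large. In Cy5 the real split gave 12 and the highest other 14, in the split that joins BRB pool 7 with BRB+NMBA pools 10 and 11, which share a day, with 3 splits as large, so the number of lists passing does not set the real split apart.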
